A study of Mus musculus with 9 samples.

How the data were processed

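Total RNA of 9 samples was hybridised to Affymetrix Mouse Transcriptome Arrays, per the labels. The samples formed 3 groups of 3: purchased mouse embryonic stem cells (mESC), Sox2-GFP+ cells of the incisor epithelium at E14.5, and Sox2-GFP+ cells of the labial cervical loop at postnatal day 30. Living fluorescent cells were sorted by flow cytometry, and each dental sample combined several animals, per the labels. Groups and replicate numbers were taken from the sample titles.

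The authors deposited log2 signals per transcript cluster for each array. Affymetrix Expression Console, Transcriptome Analysis Console and RMA, a method of background correction, normalisation and probe summary, are named without versions or roles per the submitters' processing notes. The deposited tables name a variant called SST-RMA, whose steps are not recorded in the sources used here. RMA normalises arrays to one another, so a change shared by most genes would not be seen, and it compresses differences of dim probe sets. The genome build of the coordinates is not given in the sources used here. Of 30162 single-gene clusters whose symbol is in the gene table of mouse assembly GRCm38.p6, 99.17% overlapped that gene's position. The authors also deposited, for each comparison, bi-weight mean log2 signals, signed linear fold changes, p-values from an analysis of variance and adjusted p-values, per the file headers. The deposited tables carry no detection calls. The columns of a second deposited summary carry the same values (9 of 9 columns identical over 72688 entries). Their names show the group and a digit string read here as a processing day, but not the sample. Columns were not matched to samples by value for the fits, so day was used only with those columns. By those names, 2 adult arrays and 1 embryo array were processed on the first of 2 days, and 1 adult, 2 embryo and 3 mESC arrays on the second. There, 2 embryo columns, 1 of each day, share a name. They differed as much as other embryo pairs (standard deviation of the difference 0.403 against 0.444 and 0.399). This cannot tell 2 samples from 1 sample run on both days. They were kept as separate samples because the titles number 3 biological replicates.

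The value table held 65956 transcript clusters and 6732 control probe sets. A cluster was named where the deposited annotation gave exactly 1 gene symbol, which held for 36559 clusters of 36100 genes, and 1379 symbols were updated to the current one. The 3042 clusters with several symbols and 26355 with none were left unnamed and untested in the main setting, and this left 479 of the 511 genes of the lists measured. Not measured for this reason were, among others, the adult globin genes, Top2a, Ccnb1, Mcm7 and Pdgfra. No filter on signal was applied. The median log2 signal of the negative-control probe sets was 4.86. A gene with a group mean near or below this value has no reliable level there, and its difference understates the change.

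Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend) on the deposited log2 signals, with all 9 arrays in 1 fit of 3 group means and 6 residual degrees of freedom, so that the groups share 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over the 36559 clusters of each comparison. A cluster was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Errors written ± SE are the standard errors of the moderated fit, and ± SD is the spread over the 3 arrays of a group. Tables were handled with Python 3.11.15, pandas 2.3.3 and data.table (1.17.8), and figures drawn with matplotlib 3.10.9.

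For gene lists, 1 cluster per gene was kept, that with the highest mean over the arrays. The 34 lists of tooth, signalling, cell cycle, metabolic, immune and other cell type genes, the tests, the threshold, the rule for named genes and most alternatives were fixed before the data were examined. Each list was tested against other genes with camera at a preset correlation of 0.01, adjusted over 102 tests, with an estimated correlation and the rotation test fry as alternatives. The rule for named genes admits Sox2, the 5 largest increases and decreases whose arrays do not overlap (predicted, Riken, microRNA, receptor-segment and olfactory names aside), up to 4 members of each list by absolute difference, and the called members of a list where these are 5 or fewer. From the genes the rule admits, those the text describes were picked after their values were seen, for known function and for calls that did not hang on a single array, so they are steadier than the whole set. Of 85 called genes among 140 admitted for embryo against adult, 13 lost their call when some 1 array was left out, as did 2 of 101 for embryo against mESC and 4 of 115 for adult against mESC.

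The overlap of calls between comparisons that share a group was set beside that of independent lists and beside 20 simulations of unchanged groups. Each simulation redrew all 9 arrays around the mean of each cluster over the 9. The fit was tested on simulated data made from the 9 arrays' means and spread, with 50 genes changed at each of 4 sizes among 36559. For embryo against adult it recovered 94% of changes of 1.5 log2 units, 96% of 2, 100% of 3 and 98% of 4, with 3 unchanged genes called. For embryo against mESC the shares were 92%, 98%, 98% and 98% with 4 unchanged genes called, and for adult against mESC 94%, 96%, 96% and 100% with 2.

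Alternatives changed 1 choice at a time: quantile normalisation, median centring, only clusters brighter than the median, all clusters, 1 cluster per gene, the mean of all clusters of a gene, a variance trend with robust estimation, array weights, the groups compared alone, a replicate block, both thresholds, and each array left out. The second table of values was not run as an alternative because it is identical. Chosen after seeing the data were the processing day as a block, each day alone, the embryo columns of 1 name averaged, and naming clusters of several symbols by their only symbol that is no microRNA, snoRNA, predicted or Riken name.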

Results

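RNA levels were measured on whole-transcript microarrays in 3 kinds of mouse cells, with 3 samples each. The first were purchased mouse embryonic stem cells (mESC), the pluripotent cells of the early embryo kept in culture. The second were living cells sorted by green fluorescence from the incisor epithelium of Sox2-GFP embryos at E14.5 (embryo), and the third were sorted in the same way from the labial cervical loop of Sox2-GFP mice at postnatal day 30 (adult). The labial cervical loop is the epithelial niche at the base of the mouse incisor, a tooth that grows throughout life. Sox2 encodes a transcription factor found in pluripotent cells and in dental epithelial stem cells. The labels call the samples biological replicates, and each dental sample held cells of several animals. Nothing states that the mESC samples were separate cultures, so their p-values measure only the spread between these samples, which may be technical. That spread also enters the shared estimate behind embryo against adult. The mESC arrays deviated least from their group mean (SD 0.17 to 0.206 log2, against 0.223 to 0.345 on the dental arrays). Sharing the estimate can therefore understate the spread behind embryo against adult. A fit of embryo and adult alone, without the mESC arrays and with fewer arrays to estimate the spread, called 1965 clusters against 2366 with all arrays. Which of these lowered the count was not tested.

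The 9 arrays grouped by cell type. Across 36559 transcript clusters, the correlation between arrays of a group was 0.995 to 0.996 for mESC, 0.99 to 0.995 for adult and 0.993 to 0.995 for embryo, and these are correlations across genes, which are not independent replicates. Between groups it was 0.964 to 0.978 for adult and embryo, 0.953 to 0.961 for embryo and mESC, and 0.929 to 0.94 for adult and mESC. The first principal component held 66.7% of the variance and the second 20.7%. Adult replicate 1 stood farthest from its own group, with a standard deviation of 0.345 (log2) around the group mean against 0.17 to 0.255 on the other 8 arrays. Precision is limited by the number of arrays.

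Sox2, the gene behind the sort, lies on chromosome 3 from 34650005 to 34652461 in the coordinates of the authors' annotation and is a protein-coding gene. Its log2 signals were 14.31, 14.18 and 13.99 on the mESC arrays, 11.68, 12.24 and 11.66 on the embryo arrays, and 8.75, 10.49 and 10.26 on the adult arrays. Sox2 was higher in mESC than in embryo cells (log2 embryo minus mESC -2.3 ± 0.42 SE, adjusted p = 0.0051) and than in adult cells (-4.33 ± 0.42, adjusted p = 0.000126). It was also higher in embryo than in adult cells (2.03 ± 0.42, adjusted p = 0.015). That last call was lost without embryo replicate 2 (1.84, adjusted p = 0.0603) and in a fit of only the arrays of the 2 groups compared (adjusted p = 0.0665).

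**Figure D1:**
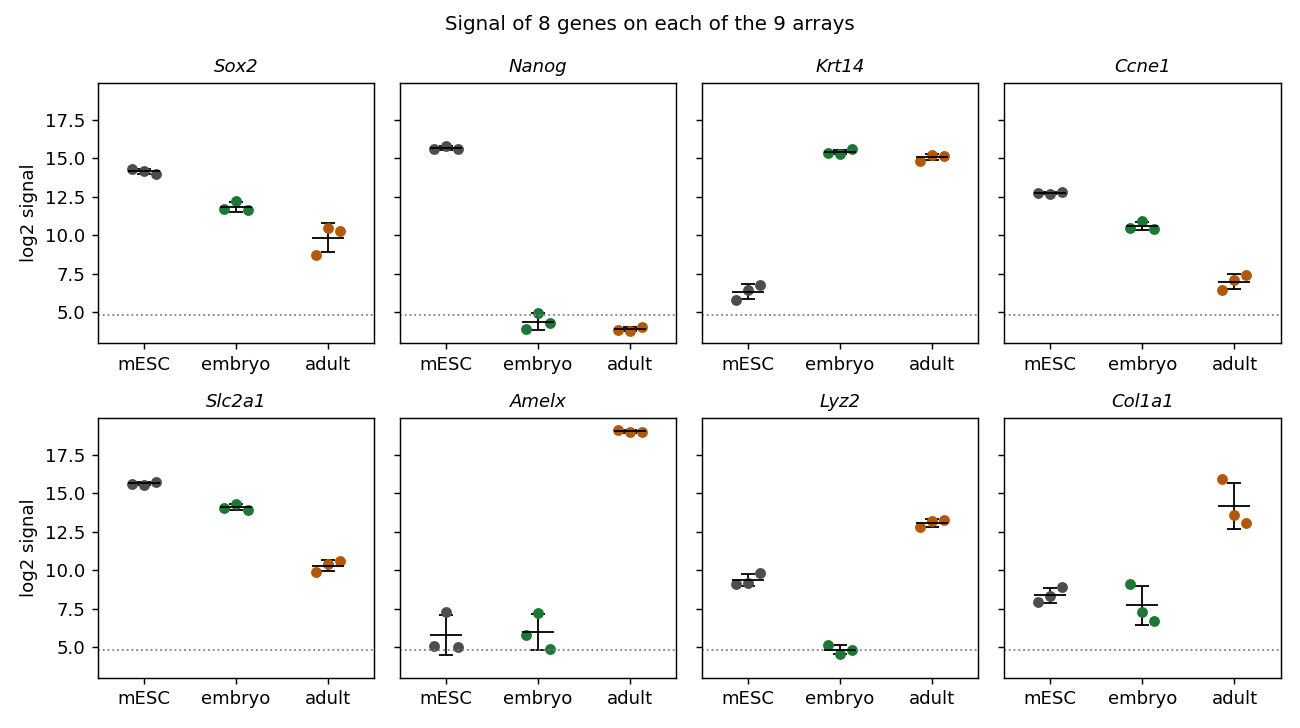
Log2 signal (vertical axis) of 8 genes on each of the 9 arrays. Points are arrays, horizontal bars are group means, whiskers are ± 1 SD (n = 3), and the dotted line marks 4.86, the median signal of the negative-control probe sets. Sox2 was highest in mESC (mean 14.16) and lowest in adult (9.83), Amelx reached 19.02 in adult, and Col1a1 varied most within groups (SD 1.51 in adult and 1.25 in embryo).

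The comparison of embryo with adult cells asked how dental Sox2-GFP+ cells differ between the forming and the mature incisor. Many genes of cell division, sugar breakdown and ribosome assembly were higher in the embryonic cells, whereas many enamel matrix genes and markers of macrophages and bone, and some of mesenchyme, were higher in the adult cells. These lists were called with a preset correlation but not with an estimated one (adjusted p = 0.0795 to 0.244). Enamel genes had some of the largest differences. Amelx, which encodes amelogenin, the main protein of forming enamel, had a mean log2 signal of 19.02 ± 0.09 (SD, n = 3) in adult and 5.98 ± 1.17 in embryo, a difference (embryo minus adult) of -13.04 ± 0.73 SE. Ambn and Enam, which encode ameloblastin and enamelin, differed by -12.66 ± 0.72 and -11.02 ± 0.54. The collagenase gene Mmp13 (-11.25 ± 0.27) and Calb1, which encodes a calcium-binding protein (-10.43 ± 0.24), also had large decreases. The embryo signals of these 2 genes (4.48 and 4.21) lay under the 4.86 of negative controls, so their size is bounded by the background and does not rank them.

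The largest increases in embryo cells were Slc38a4, an amino acid transporter gene (5.36 ± 0.69), Capn6, which encodes a calpain family protein (5.3 ± 0.19), the tubulin gene Tubb2b (4.71 ± 0.13), Pcyt1b, a gene of phosphatidylcholine synthesis (4.55 ± 0.39), and Tubb2a-ps2 (4.27 ± 0.17). Tubb2a-ps2 is a near-identical copy of Tubb2a, so its signal may come from either. In all, 2366 clusters were called, 1321 higher and 1045 lower in embryo, and 2364 of these had the 3 arrays of one group entirely above the 3 of the other. Such separation held for 27.8% of all clusters tested, against 10% by chance. The share of calls that were higher was 55.8%, and it was 46.1% under quantile normalisation. Differences of at least 16-fold were mostly decreases, 104 against 8 increases.

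Of the 25 measured genes of the cell cycle and proliferation list, 23 were higher in embryo cells and none lower, with a median difference of 1.74. Ccne1, which encodes cyclin E1 (3.61 ± 0.24), Rrm2 of nucleotide synthesis (2.24 ± 0.22), and the mitotic regulators Bub1 (2.17 ± 0.14) and Cdc20 (2.16 ± 0.15) were among them. The camera set test gave adjusted p = 1.87e-22 with a preset correlation and adjusted p = 0.0935 with an estimated correlation. For glycolysis, 8 of 14 genes were higher, among them the glucose transporter gene Slc2a1 (3.79 ± 0.18), Pgk1 (2.41 ± 0.18) and Tpi1 (2.25 ± 0.14), and the test gave adjusted p = 7.3e-09 (adjusted p = 0.0795 with an estimated correlation). For ribosome biogenesis, 11 of 17 genes were higher, among them Mybbp1a (1.65 ± 0.13), with adjusted p = 2.65e-13 (adjusted p = 0.112 with an estimated correlation). Among 8 DNA methylation enzymes, Uhrf1 (2.55 ± 0.17) and the maintenance methyltransferase gene Dnmt1 (1.21 ± 0.1) were higher, with adjusted p = 0.000739 (adjusted p = 0.112 with an estimated correlation). Igf2bp2 (3.11 ± 0.11) and Igf2bp3 (2.96 ± 0.2), fetal RNA-binding protein genes, were the 2 of 8 genes of the Lin28 and oncofetal axis that were higher, and the list as a whole was not called (adjusted p = 0.0523), but it lay close to the threshold. It passed without adult replicate 1 (adjusted p = 0.0349) or embryo replicate 1 (adjusted p = 0.0435), with the processing day as a block (adjusted p = 0.0341), quantile normalisation (adjusted p = 0.0267), array weights (adjusted p = 0.0362) and the embryo columns of 1 name averaged (adjusted p = 0.0477). So it did with a variance trend (adjusted p = 0.0499) and clusters of several symbols named (adjusted p = 0.0036), and in fry (adjusted p = 4.59e-05). The CDK inhibitor and quiescence list had 3 of 13 genes lower in embryo, among them Gas6, a growth-arrest-specific gene (-5.59 ± 0.26). Its test gave adjusted p = 0.0376 (adjusted p = 0.153 with an estimated correlation), and that call was lost without adult replicate 1 (adjusted p = 0.0578), embryo replicate 1 (adjusted p = 0.111), mESC replicate 1 (adjusted p = 0.0509) or mESC replicate 3 (adjusted p = 0.0586), and with the processing day as a block (adjusted p = 0.0513). It was lost as well with array weights (adjusted p = 0.0594), among the brighter clusters (adjusted p = 0.0613) and with the embryo columns of 1 name averaged (adjusted p = 0.0555). Markers of other cell types differed between the same samples, in the direction opposite to the lists that were higher in embryo cells. Macrophage and mesenchyme genes were higher in adult cells by medians of 2.79 and 1.2 log2 units (embryo minus adult -2.79 and -1.2).

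The ameloblast and enamel matrix list had 9 of 16 genes lower in embryo cells and 1 higher, a call lost without embryo replicate 2 or embryo replicate 3, with a median of -4.43 and adjusted p = 9.47e-11 (adjusted p = 0.112 with an estimated correlation). Adult replicate 1, the array farthest from its group, held the highest adult value for 14 of the 16. The BMP, activin and TGF-beta list had 4 of 22 genes lower, which included the ligand genes Tgfb3 (-4.9 ± 0.56) and Bmp4 (-2.48 ± 0.28) and the receptor gene Tgfbr2 (-4.65 ± 0.23), with adjusted p = 0.00321 (adjusted p = 0.314 with an estimated correlation). Here too adult replicate 1 held the highest adult value for most genes, 15 of the 22. For dental and oral epithelium transcription factors, 5 of 20 were higher and 2 lower in embryo, and 3 were higher without adult replicate 1. Lef1, a Wnt effector gene, was 1 of the 5 (2.4 ± 0.41). Wnt pathway genes were 2 higher and 5 lower of 29, with the inhibitor gene Wif1 at -2.92 ± 0.44, and adult replicate 1 held the highest adult value for 19 of the 29. FGF pathway genes were 3 higher and 1 lower of 18, and the 3 were the ligand gene Fgf15 (2.83 ± 0.36) and the feedback genes Dusp6 (2.26 ± 0.25) and Spry2 (1.7 ± 0.14). The Hedgehog receptor gene Ptch1 (-1.67 ± 0.18) was 1 of 2 lower genes of 13 in the Hedgehog list and 1 of 2 of 11 incisor stem cell markers. The Notch list had 2 of 14 lower, among them Hey1 (-2.34 ± 0.33), and in the Eda and NF-kappaB list the ectodysplasin receptor gene Edar was the 1 of 12 that was higher (1.5 ± 0.21), with 1 lower. Epithelial keratins and junctions went both ways, 4 higher and 8 lower of 25, with Cldn4 at 3.7 ± 0.2. In camera these last 7 lists and the transcription factors were not called, with the smallest adjusted p = 0.112 for the transcription factors, which passed without adult replicate 2 (adjusted p = 0.04). FGF genes passed in fry, which asks if a list moves one way without setting it against other genes (adjusted p = 0.00429), and with clusters of several symbols named (adjusted p = 0.0365). Wnt genes passed among the brighter clusters (adjusted p = 0.0436).

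Among the markers of other cells, 11 of 15 macrophage and leukocyte genes were lower in embryo than in adult cells and none higher, with a median of -2.79 and adjusted p = 3.53e-15 (adjusted p = 0.0935 with an estimated correlation). Lyz2 (-8.22 ± 0.23), C1qb (-6.53 ± 0.14) and Csf1r (-5.36 ± 0.36), which encode lysozyme, a complement component and the receptor of a macrophage growth factor, were among them. Of the dental and jaw mesenchyme genes, 5 of 18 were lower in embryo, which included the collagen gene Col1a1 (-6.45 ± 0.84) and Lum (-5.2 ± 0.92), with adjusted p = 3.91e-07 (adjusted p = 0.244 with an estimated correlation). That count was 3 without adult replicate 2, embryo replicate 2, embryo replicate 3 or any mESC replicate. Adult replicate 1, the array farthest from its group, held the highest adult value for 16 of the 18 genes, and without it the median was -0.72 against -1.2. Osteoblast and odontoblast genes were 6 lower of 10, with Spp1 at -4.79 ± 0.43, and adjusted p = 2.07e-06 (adjusted p = 0.151 with an estimated correlation). Adult replicate 1 held the highest adult value for 9 of the 10. Endothelial genes were 2 lower of 10 (adjusted p = 0.000823, and adjusted p = 0.138 with an estimated correlation). Of 10 neutrophil and granule genes limma called 0, with 3 at an unadjusted p under 0.05, although the set test passed (median -0.42, adjusted p = 0.00214, and adjusted p = 0.155 with an estimated correlation). That set test did not pass among the brighter clusters alone (adjusted p = 0.209). Camera called no list among Schwann cells and glia (1 higher, 2 lower of 11), neurons (1 higher of 11), erythroid genes (1 lower of 7), skeletal muscle and cornified and oral mucosa keratinocytes. Fry passed for neurons (adjusted p = 0.029) and cornified keratinocytes (adjusted p = 0.024). For skeletal muscle and cornified keratinocytes limma called 0 of 9 and 0 of 11, with 1 and 2 at an unadjusted p under 0.05.

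Of the 7 measured MHC class I and antigen processing genes, 3 were lower in embryo, among them B2m (-3.99 ± 0.22) and H2-K1 (-1.3 ± 0.1), which encode both chains of a class I molecule, with adjusted p = 8.56e-08 (adjusted p = 0.112 with an estimated correlation). Interferon-stimulated genes were 2 lower of 17 (adjusted p = 6.06e-05, adjusted p = 0.118 with an estimated correlation and adjusted p = 0.0532 among the brighter clusters), and epithelial innate defence genes were 2 lower of 15 (adjusted p = 0.0115, and adjusted p = 0.328 with an estimated correlation). These 3 lists moved in the same direction as the macrophage markers (median -2.79). Adult replicate 1, the array farthest from its group, held the highest adult value for 5 of the 7, 12 of the 17 and 9 of the 15 genes. Immediate early and dissociation stress genes were 2 lower of 18 and the list was not called (adjusted p = 0.095), but it passed without embryo replicate 1 (adjusted p = 0.0212) or embryo replicate 2 (adjusted p = 0.00693), with median centring (adjusted p = 0.0312) and with the embryo columns of 1 name averaged (adjusted p = 0.0125). Naive and core pluripotency genes (2 lower of 27), fetal growth and imprinted genes (1 higher of 12), germline genes and sex-linked genes were not called as lists. Of the germline and sex-linked genes limma called 0 of 15 and 0 of 5, with 1 of each at an unadjusted p under 0.05. The imprinted and sex-linked lists passed without adult replicate 1 (adjusted p = 0.0198 and adjusted p = 0.0163), and sex-linked genes under quantile normalisation (adjusted p = 0.033).

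The arrays were processed on 2 days, and both days held embryo and adult arrays. With the day as a block 2276 clusters were called, and the median of the cell cycle list was 1.78 (1.9 within the first day and 1.59 within the second), of glycolysis 1.28 (1.41 and 1.19), of ribosome biogenesis 1.2 (1.36 and 1), of the enamel list -4.28 (-4.8 and -3.78), of the macrophage list -2.81 (-3.07 and -2.7), of mesenchyme -1.09 (-1.6 and -0.56) and of osteoblasts -2.72 (-3.36 and -2). With the arrays of the second day alone, of which 1 was adult, 1406 clusters were called and Col1a1 (-5.15, adjusted p = 0.0751), Lum (-3.73, adjusted p = 0.155) and Ptch1 (-1.48, adjusted p = 0.0772) were not. With those of the first day alone limma called 0 clusters, with 1 residual degree of freedom and 5603 clusters at an unadjusted p under 0.05. Adjusted over the list alone, counts equalled those over all clusters for 28 of the 34 lists; the other 6 gave 7 higher for the dental transcription factors, 5 higher for epithelial keratins and junctions, 1 higher and 5 lower for BMP, activin and TGF-beta, 1 higher for Notch, 8 lower for mesenchyme and 9 lower for osteoblasts. Of 15 lists called with the preset correlation, 0 were called with the estimated one. Beside mesenchyme, medians of called lists that shrank by over 1.5 times on the second day were those of neutrophils (-0.16 against -0.42), interferon-stimulated genes (-0.17 against -0.34), BMP, activin and TGF-beta (-0.14 against -0.27) and innate defence (-0.03 against -0.12). That of CDK inhibitors grew (-0.26 against -0.07). For the incisor stem cell and Hedgehog lists, neither of them called, median and mean differed in sign (0.12 and -0.17, and 0.11 and -0.51), and both medians were -0.01 under quantile normalisation.

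**Figure D2:**
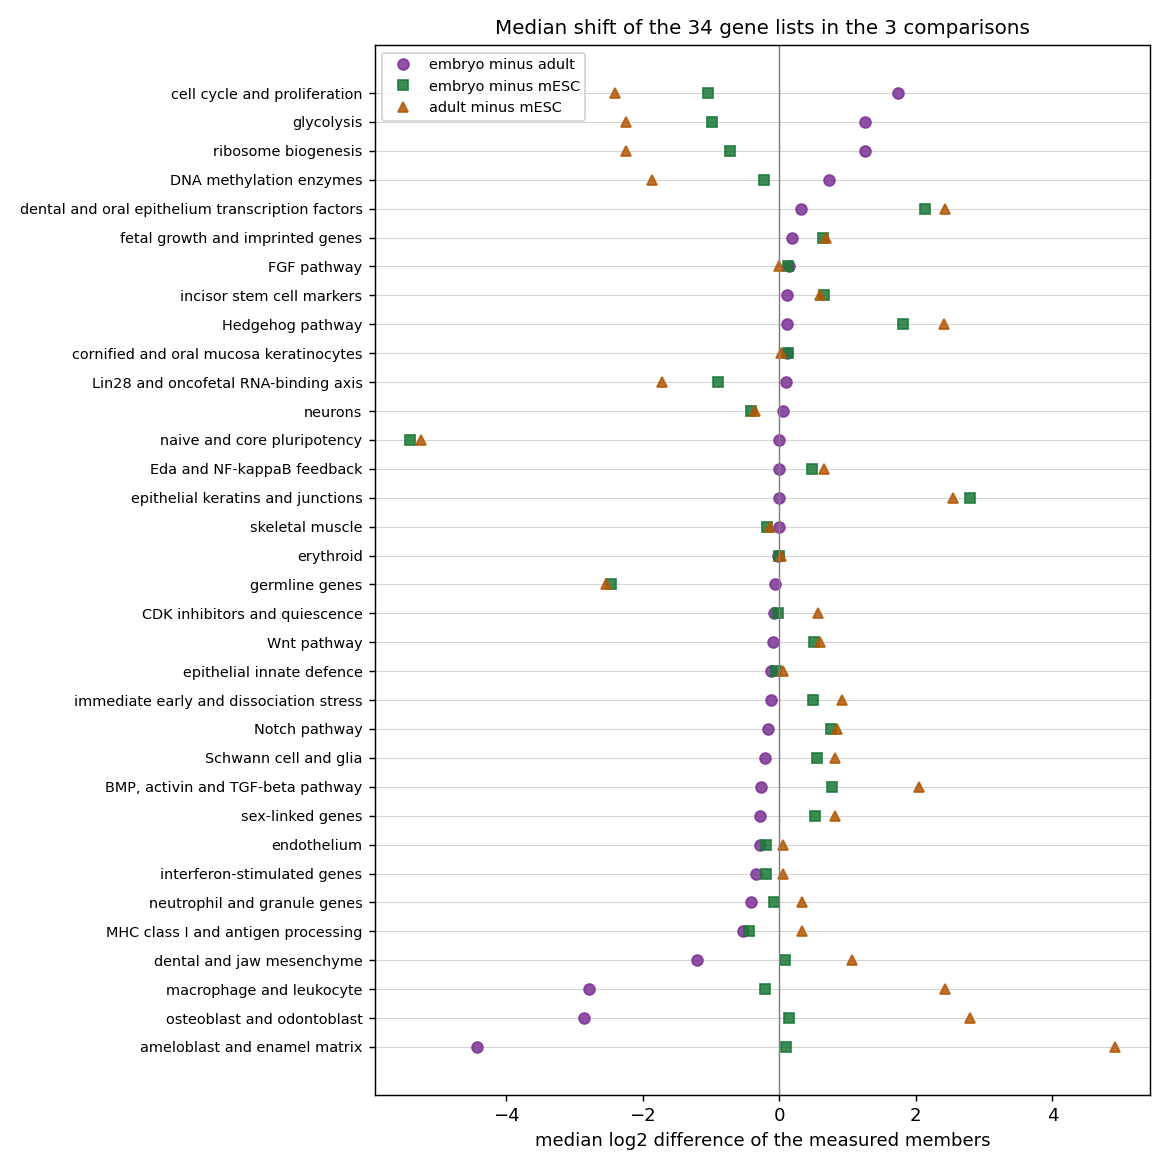
Median log2 difference (horizontal axis) of the measured members of each of the 34 gene lists (vertical axis, ordered by embryo minus adult), with 1 symbol per comparison. The cell cycle list lies at 1.74 for embryo minus adult, -1.04 for embryo minus mESC and -2.4 for adult minus mESC, and the enamel list at -4.43, 0.1 and 4.92.

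Embryonic dental cells were next compared with mESC. Pluripotency and germline genes were far lower in the dental cells, and most keratins, junction genes and transcription factors of dental epithelium were higher. With an estimated correlation the lists of the first 2 kinds were called, and those of keratins and junctions (adjusted p = 0.112) and of transcription factors (adjusted p = 0.103) were not. The keratin genes Krt5 (embryo minus mESC 10.13 ± 0.36 SE) and Krt14 (9.06 ± 0.23) of basal epithelium, the desmosome gene Dsc3 (11.15 ± 0.31), Cyp26c1, which encodes an enzyme that degrades retinoic acid (11.17 ± 0.4), and the semaphorin gene Sema3d (8.66 ± 0.09) were among the largest increases. Krt14 had a mean signal of 15.41 ± 0.15 (SD, n = 3) in embryo and 6.35 ± 0.48 in mESC. Among the largest decreases were the pluripotency genes Dppa5a (-13.2 ± 0.28), Nanog (-11.27 ± 0.24) and Tdgf1 (-10.63 ± 0.11), Tdgf1-ps1 (-13.04 ± 0.09), a near-identical copy whose signal cannot be separated from that of Tdgf1, and the phospholipase gene Pla2g1b (-10.15 ± 0.13). In total 4068 clusters were called, 1833 higher and 2235 lower in embryo, and 42.1% of all clusters tested had fully separated arrays, against 10% by chance. The share of calls that were higher was 45.1%, and it was 56.2% with each array centred on its median.

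Of 27 naive and core pluripotency genes, 25 were lower in embryonic dental cells and none higher (median -5.4, adjusted p = 3.43e-26). Of 15 germline genes, 11 were lower (median -2.47, adjusted p = 5.89e-13), among them Tdrd12 (-8.63 ± 0.09), Hormad1 (-6.33 ± 0.2) and Mael (-5.86 ± 0.12), genes of meiosis and transposon silencing whose embryo signals (4.36, 4.15 and 3.88) lay under the 4.86 of negative controls and bound these differences. Both calls held with an estimated correlation (adjusted p = 0.0189 and adjusted p = 0.0251), the only 2 of the 20 called lists of this comparison that did. In the opposite direction, 17 of 25 epithelial keratin and junction genes were higher and 3 lower (adjusted p = 1.62e-11, and adjusted p = 0.112 with an estimated correlation). Dental and oral transcription factors were 16 higher of 20, among them Isl1 (8 ± 0.28) and the epithelial regulator Trp63 (5.96 ± 0.26), with adjusted p = 5.87e-14 (adjusted p = 0.103 with an estimated correlation). Incisor stem cell markers were 5 higher of 11, which were Igfbp5 (8.07 ± 0.38), Tnfrsf19 (5.76 ± 0.29), the polycomb gene Bmi1 (3 ± 0.17), Gli1 and Ptch1, with adjusted p = 1.51e-07 (adjusted p = 0.0795 with an estimated correlation).

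Some genes of each signalling list were also higher in embryonic dental cells, and no signalling list was called with an estimated correlation. The Hedgehog list had 8 of 13 higher, with the ligand gene Shh at 5.78 ± 0.38 (adjusted p = 2.98e-08, and adjusted p = 0.0935 with an estimated correlation). The BMP, activin and TGF-beta list had 10 higher and 1 lower of 22, with Tgfb2 (6.61 ± 0.37), the BMP antagonist gene Bambi (6.21 ± 0.24) and Bmp7 (5.06 ± 0.17) (adjusted p = 3.91e-07, and adjusted p = 0.121 with an estimated correlation). The Wnt list had 7 higher and 1 lower of 29, with Wif1 (6.26 ± 0.44) and Wnt5a (2.62 ± 0.21) (adjusted p = 1.23e-06, and adjusted p = 0.118 with an estimated correlation). The FGF list had 5 higher, among them the receptor gene Fgfr2 (3.75 ± 0.25), and 1 lower of 18 (adjusted p = 0.0102, and adjusted p = 0.154 with an estimated correlation). For Notch, 7 were higher, among them Jag1 (2.2 ± 0.26), and Notch3 was lower (-1.96 ± 0.1) of 14 (adjusted p = 0.00321, and adjusted p = 0.103 with an estimated correlation). In the Eda list 3 of 12 were higher, among them Edaradd (4.75 ± 0.36), and Eda2r was lower (-3.01 ± 0.19), with adjusted p = 0.00489 (adjusted p = 0.105 with an estimated correlation).

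Cell cycle genes were 13 lower and 1 higher of 25 in embryonic dental cells against mESC (median -1.04, adjusted p = 0.000116, and adjusted p = 0.318 with an estimated correlation). Ccne1 (-2.15 ± 0.24) and the mitotic kinase gene Aurka (-1.87 ± 0.12) were lower, whereas Mki67, a marker of dividing cells, was higher (1.2 ± 0.2). Glycolysis genes were 7 lower of 14, among them the glucose transporter gene Slc2a3 (-7.24 ± 0.11), with adjusted p = 0.000328 (adjusted p = 0.118 with an estimated correlation), and ribosome biogenesis genes were 7 lower of 17, among them Rrp9 (-1.8 ± 0.11), with adjusted p = 6.46e-06 (adjusted p = 0.253 with an estimated correlation). The DNA methylation enzymes moved both ways and the list was not called (adjusted p = 0.342). The methyltransferase gene Dnmt3b (-4.73 ± 0.11) and the demethylation gene Tet1 (-4.71 ± 0.26) were lower, and Tet3, also of demethylation, was higher (4.49 ± 0.27). Trim71, a gene of the Lin28 axis, was lower (-5.4 ± 0.31), and that list was not called (adjusted p = 0.182).

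Macrophage markers (1 higher, 3 lower of 15) and mesenchyme markers (1 higher of 18, Dcn at 5.13 ± 0.61) were not called as lists between embryonic dental cells and mESC (adjusted p = 0.328 and adjusted p = 0.112). Mesenchyme passed without mESC replicate 3 (adjusted p = 0.0478). The immediate early list had 1 of 18 higher, Jun (5.66 ± 0.93), and was not called (adjusted p = 0.0523). Jun was 13.99 and 14.09 on embryo arrays 1 and 2 but 10.28 on the third, and without embryo replicate 3 the list had 8 higher (adjusted p = 1.08e-05). It also passed without mESC replicate 3 (adjusted p = 0.0402) and with a variance trend (adjusted p = 0.0467). Xist, the transcript that silences 1 X chromosome in female cells, was higher in embryo (8.01 ± 0.27), at 14.17 against 6.16 in mESC.

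The set tests of 6 further lists passed in this comparison. Sex-linked genes were 2 higher of 5, Xist and the Y-linked Kdm5d (2.38 ± 0.2), with adjusted p = 0.00262 (adjusted p = 0.141 with an estimated correlation). Imprinted genes were 4 higher and 2 lower of 12, among them the growth factor gene Igf2 (2.47 ± 0.27) and Peg10 (-5.24 ± 0.48), with adjusted p = 0.00463 (adjusted p = 0.379 with an estimated correlation). That call was lost with each array centred on its median (adjusted p = 0.0574). Cornified and oral mucosa keratinocyte genes were 1 higher of 11, Krt10 (1.26 ± 0.16), with adjusted p = 0.0118 (adjusted p = 0.138 with an estimated correlation). The enamel list was 2 higher of 16, Enam (2.8 ± 0.54) and Tuft1 (1.55 ± 0.09), with adjusted p = 0.0213 (adjusted p = 0.457 with an estimated correlation), and was lost with the day as a block (adjusted p = 0.0599). Its median of 0.1 turned sign, to -0.14 under the block and -0.01 on the second day. Enam was not called on the second day alone (2.36, adjusted p = 0.0681). Neurons were 1 higher and 4 lower of 11, among them the growth cone gene Stmn2 (-5.53 ± 0.1), with adjusted p = 0.0326 (adjusted p = 0.287 with an estimated correlation, and adjusted p = 0.0507 without adult replicate 1). Schwann cell genes were 1 higher of 11, Erbb3 (1.66 ± 0.19), with adjusted p = 0.0418 (adjusted p = 0.457 with an estimated correlation), which was lost without embryo replicate 1 (adjusted p = 0.129), adult replicate 2 (adjusted p = 0.0526), mESC replicate 1 (adjusted p = 0.0586) or mESC replicate 2 (adjusted p = 0.069).

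Other settings ended calls of weaker lists in this comparison. Among the brighter clusters alone, with fewer genes tested, the lists lost were Schwann cells (adjusted p = 0.276), neurons (adjusted p = 0.206), cornified keratinocytes (adjusted p = 0.128), enamel (adjusted p = 0.101), Eda and imprinted genes (each adjusted p = 0.0676) and Notch (adjusted p = 0.0614). Quantile normalisation ended the calls of Schwann cells (adjusted p = 0.119), enamel (adjusted p = 0.0917) and Eda genes (adjusted p = 0.0507). Median centring ended those of enamel (adjusted p = 0.15) and Schwann cells (adjusted p = 0.145). Schwann cells were lost with array weights too (adjusted p = 0.0577), and with clusters of several symbols named (adjusted p = 0.0636).

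The other lists were not called between embryonic dental cells and mESC. These were the CDK inhibitors (2 higher, 3 lower of 13), osteoblasts (1 higher, 1 lower of 10), endothelium (1 lower of 10, Pecam1 at -4.07 ± 0.08), neutrophils (1 higher of 10), interferon-stimulated genes (2 lower of 17, with Bst2 at -6.35 ± 0.2) and skeletal muscle (2 lower of 9). For MHC class I, innate defence and erythroid genes limma called 0 of 7, 0 of 15 and 0 of 7, with 6, 1 and 1 at an unadjusted p under 0.05. MHC class I passed without adult replicate 1 (adjusted p = 0.0275), adult replicate 2 (adjusted p = 0.0422), adult replicate 3 (adjusted p = 0.0366) or embryo replicate 1 (adjusted p = 0.038). It also passed with the day as a block (adjusted p = 0.0461), quantile normalisation (adjusted p = 0.0384), median centring (adjusted p = 0.0337), array weights (adjusted p = 0.0399) and the embryo columns of 1 name averaged (adjusted p = 0.0482), and in fry (adjusted p = 0.00988). Interferon-stimulated genes passed without adult replicate 1 (adjusted p = 0.0491) or embryo replicate 1 (adjusted p = 0.0311), and skeletal muscle without embryo replicate 1 (adjusted p = 0.0283), embryo replicate 3 (adjusted p = 0.0439), mESC replicate 1 (adjusted p = 0.0349) or mESC replicate 2 (adjusted p = 0.0499). In fry, further lists passed: DNA methylation enzymes (adjusted p = 2.19e-05), the Lin28 axis (adjusted p = 2.24e-05), skeletal muscle (adjusted p = 0.000113), endothelium (adjusted p = 0.000138), interferon-stimulated genes (adjusted p = 0.000559) and macrophages (adjusted p = 0.0117). Enamel genes (adjusted p = 0.117) and Schwann cells (adjusted p = 0.156) did not. The Lin28 axis passed in camera with median centring (adjusted p = 0.0331) and with clusters of several symbols named (adjusted p = 0.038), and skeletal muscle with array weights (adjusted p = 0.0433). Medians and means differed in sign for osteoblasts (0.14 and -0.25) and neutrophils (-0.07 and 0.3), and the median of the CDK inhibitors (-0.02) was opposite in sign to their set test. Under quantile normalisation the medians of neutrophils and CDK inhibitors were positive (0.04 and 0.16). Adjusted over the list alone, 32 of 34 lists kept their counts; Wnt gave 2 lower and imprinted genes 3 lower, against 1 and 2 over all clusters. With the processing day as a block 4000 clusters were called, with the arrays of the second day alone 3885, and no list median moved by more than 0.24 under the block or 0.31 on the second day. All mESC arrays were of the second day. Hybridisation controls averaged 10.30 to 10.74 on the mESC arrays and 9.41 to 9.59 on all 6 dental arrays, a technical difference that goes with the groups in both comparisons with mESC.

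Adult dental cells differed from mESC at more genes than embryonic cells did, with 6335 clusters called, 2562 higher and 3773 lower in adult, and 47.7% of all clusters tested fully separated. Whether the numbers of calls differ was not tested. Enamel genes were among the largest increases, with Enam at 13.81 ± 0.54 SE (adult minus mESC), Ambn at 13.48 ± 0.72 and Amelx at 13.21 ± 0.73, followed by Krt5 (10.68 ± 0.36) and Mmp13 (10.63 ± 0.27). Large decreases were seen at the same 5 genes as in embryo, which were Tdgf1-ps1 (-13.01 ± 0.09), Dppa5a (-12.5 ± 0.28), Nanog (-11.73 ± 0.24), Tdgf1 (-10.61 ± 0.11) and Pla2g1b (-10.22 ± 0.13). Nanog had a mean signal of 3.92 ± 0.13 (SD, n = 3) in adult cells, below the 4.86 of negative controls, so its difference is bounded by the background of the array. The same held for Tdgf1-ps1, Tdgf1 and Pla2g1b, with adult means of 2.95, 4 and 3.58.

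The enamel list had 9 of 16 genes higher in adult cells (median 4.92, adjusted p = 4.15e-11, and adjusted p = 0.112 with an estimated correlation). Pluripotency genes were 24 lower of 27 (adjusted p = 6.31e-21) and germline genes 11 lower of 15 (adjusted p = 2.42e-10), and both calls held with an estimated correlation (adjusted p = 0.0189 and adjusted p = 0.0363). Transcription factors of dental epithelium were 12 higher and 1 lower of 20, with Dlx3 (7.25 ± 0.48) and Isl1 (6.92 ± 0.28) (adjusted p = 1.46e-08, and adjusted p = 0.121 with an estimated correlation). Hedgehog genes were 8 higher of 13, with Shh at 6.78 ± 0.38 (adjusted p = 3.46e-07, and adjusted p = 0.103 with an estimated correlation). The BMP, activin and TGF-beta list had 16 higher of 22, among them Bambi (6.81 ± 0.24), Tgfb2 (6.49 ± 0.37) and Tgfbr2 (5.04 ± 0.23), with adjusted p = 2.48e-10 (adjusted p = 0.105 with an estimated correlation). The Wnt list held Wif1 (9.18 ± 0.44), with 10 higher and 1 lower of 29 (adjusted p = 4.24e-05, and adjusted p = 0.143 with an estimated correlation), and Igfbp5 (9.83 ± 0.38) was among the 5 of 11 incisor stem cell markers that were higher (adjusted p = 0.000132, and adjusted p = 0.107 with an estimated correlation).

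Cell cycle genes were 23 lower of 25 in adult cells against mESC and none higher (median -2.4, adjusted p = 4.17e-13, and adjusted p = 0.112 with an estimated correlation), with Ccne1 at -5.76 ± 0.24 and Aurka at -3.74 ± 0.12. Glycolysis genes were 13 lower of 14, with Slc2a3 (-7.72 ± 0.11) and Slc2a1 (-5.34 ± 0.18) (adjusted p = 7.79e-09, and adjusted p = 0.0795 with an estimated correlation). Ribosome biogenesis genes were 15 lower of 17, among them Rrp9 (-3.05 ± 0.11) and the polymerase gene Polr1b (-2.73 ± 0.23), with adjusted p = 5.28e-10 (adjusted p = 0.138 with an estimated correlation). Gas6 was higher (4.01 ± 0.26) in the CDK inhibitor and quiescence list, with 3 higher and 2 lower of 13 (adjusted p = 0.0182, and adjusted p = 0.126 with an estimated correlation). Dnmt3b was lower (-5.64 ± 0.11), as were 5 of 8 DNA methylation enzymes, with 1 higher (adjusted p = 0.0036, and adjusted p = 0.132 with an estimated correlation).

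Markers of some other cell types, among them macrophages, mesenchyme and osteoblasts, were higher in adult cells than in mESC, and how adult and embryonic cells differ is the comparison of embryo with adult above. Macrophage markers were 11 higher and 1 lower of 15 (median 2.42, adjusted p = 4.27e-08, and adjusted p = 0.118 with an estimated correlation), with Tyrobp (6.81 ± 0.41), C1qb (6.52 ± 0.14) and Csf1r (6.38 ± 0.36). Mesenchyme markers were 8 higher of 18, with Lum (6.8 ± 0.92) and Dcn (6.27 ± 0.61), and adjusted p = 3.17e-06 (adjusted p = 0.285 with an estimated correlation). B2m was higher (3.45 ± 0.22), the 1 of 7 MHC class I genes, with adjusted p = 0.00214 (adjusted p = 0.244 with an estimated correlation). Immediate early genes were 6 higher of 18, with Fos at 5.09 ± 1.08, and adjusted p = 0.00653 (adjusted p = 0.513 with an estimated correlation), and the count was 3 without adult replicate 2, mESC replicate 1 or mESC replicate 2. Fos was not called with the day as a block (adjusted p = 0.0506) or on the second day alone (adjusted p = 0.145), and the immediate early list was not called with the block (adjusted p = 0.0631). Xist was higher in adult cells as well (7.39 ± 0.27).

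Of the further lists, epithelial keratins and junctions were 15 higher and 2 lower of 25, with Dsc3 at 9.45 ± 0.31 and Krt14 at 8.71 ± 0.23, and adjusted p = 1.09e-09 (adjusted p = 0.121 with an estimated correlation). Sex-linked genes were 2 higher of 5 (adjusted p = 0.000132, and adjusted p = 0.112 with an estimated correlation). Osteoblast genes were 7 higher and 1 lower of 10, with adjusted p = 0.000876 (adjusted p = 0.287 with an estimated correlation). The Lin28 axis was 6 lower of 8, with Trim71 at -5.25 ± 0.31, and adjusted p = 0.00262 (adjusted p = 0.105 with an estimated correlation). Notch genes were 6 higher and 1 lower of 14, with Hey1 at 3.39 ± 0.33, and Eda genes 5 higher and 1 lower of 12, with Edaradd at 4.4 ± 0.36; each had adjusted p = 0.00321 (adjusted p = 0.103 with an estimated correlation). Neuron genes were 4 lower of 11 (adjusted p = 0.00944, and adjusted p = 0.203 with an estimated correlation). Neutrophil genes were 1 higher of 10, the protease gene Mmp9 at 4.69 ± 0.78 (adjusted p = 0.00941, and adjusted p = 0.234 with an estimated correlation). Imprinted genes were 5 higher and 3 lower of 12 (adjusted p = 0.0206, adjusted p = 0.446 with an estimated correlation, and adjusted p = 0.0803 without adult replicate 1). Schwann cell genes were 3 higher of 11, with Ngfr at 3.59 ± 0.44 (adjusted p = 0.0216, adjusted p = 0.436 with an estimated correlation, and adjusted p = 0.0535 without adult replicate 3).

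Not called as lists were FGF genes (6 higher, 4 lower of 18), interferon-stimulated genes (1 higher, 2 lower of 17), innate defence (2 higher, 1 lower of 15), endothelium (1 higher, 1 lower of 10), erythroid genes (1 higher of 7) and skeletal muscle (2 lower of 9). Of 11 cornified and oral mucosa keratinocyte genes limma called 0, with 2 at an unadjusted p under 0.05. Median and mean differed in sign for FGF (-0.01 and 0.22), interferon-stimulated genes (0.05 and -0.24) and endothelium (0.06 and -0.17), and the FGF median was 0.05 with median centring. Among the brighter clusters alone, with fewer genes tested, the lists lost were neurons (adjusted p = 0.214), neutrophils (adjusted p = 0.168), Schwann cells (adjusted p = 0.149), imprinted genes (adjusted p = 0.101), the Lin28 axis (adjusted p = 0.0851), CDK inhibitors (adjusted p = 0.0767) and DNA methylation enzymes (adjusted p = 0.0549). Quantile normalisation ended the calls of Schwann cells (adjusted p = 0.0922), imprinted genes (adjusted p = 0.0734) and CDK inhibitors (adjusted p = 0.0553). Median centring ended that of imprinted genes (adjusted p = 0.0579). In fry, skeletal muscle (adjusted p = 0.000138) and FGF genes (adjusted p = 0.0438) passed, and Schwann cells (adjusted p = 0.0737) and immediate early genes (adjusted p = 0.163) did not. Of 27 lists called with the preset correlation 2 were called with the estimated one. Adjusted over the list alone, 30 of 34 lists kept their counts; BMP, activin and TGF-beta gave 17 higher, Notch 7, mesenchyme 9 and osteoblasts 8. With the day as a block 6173 clusters were called and with the second day alone 5596, and the median of the enamel list was 4.33 and 3.91 against 4.92. Among the lists called in this comparison, medians that moved by over 1.5 times were those of immediate early genes (0.42 with the block against 0.92), Schwann cells (1.33 with the block against 0.81), mesenchyme (0.53 on the second day against 1.07) and neutrophils (0.15 on the second day against 0.33).

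Genes that both dental groups held above or below mESC were counted next. Of the calls, 1245 clusters were higher and 1914 lower than mESC in both, against 128 and 231 for independent lists, while 32 were called in opposite directions. In 20 simulations of unchanged groups, with all arrays redrawn, the overlap was 0. Almost no cluster is called where no group differs, so that 0 does not show how much the shared arrays add. Across clusters the differences correlated at r = 0.79 against 0.5 in the simulations, with a covariance of 0.715 against 0.019. Embryo and mESC were both above adult at 876 clusters and both below at 825, against 136 and 73 for independent lists and 0 in the simulations, with 114 opposite. The correlation was 0.58 against 0.49 and the covariance 0.395 against 0.019. The shared groups of 3 arrays were not split into parts, so part of each excess may come from the shared arrays.

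The authors' deposited table of each comparison, with its own p-values, was read at the same threshold over the same clusters. The authors' deposited tables called 557 clusters for embryo against adult, 3205 for embryo against mESC and 5097 for adult against mESC. Of these, 97.8%, 96.4% and 97.6% were also called in the limma fit, with 0 in the opposite direction. The other way round, 545 of the 2366 limma calls, 3089 of 4068 and 4976 of 6335 were in the deposited calls.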

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

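The look at control signals, with its margin, and the split by processing day were chosen only after the data were seen. Spike-in probe sets outside the comparisons stood above all mESC arrays on arrays of the first processing day. Of 96 such probe sets, those at least 2 log2 units above the highest mESC array are given here. ERCC-00014, a synthetic control transcript, read 12.44 and 14.2 on the 2 adult arrays of that day, against at most 8.78 on mESC arrays. ERCC-00099 read 8.1 on an adult array (at most 4.84 on mESC) and ERCC-00145 read 9.81 (at most 6.21). The labelling control dap read 7.65 on an adult array (at most 4.54), and the control thr read 6.79 on the embryo array of that day (at most 3.83). By sample, these values of ERCC-00014 stood on adult replicates 1 and 2, and that of thr on embryo replicate 2. This places those arrays on the first day. Hybridisation controls went with the group instead, at a mean of 10.30 to 10.74 on the mESC arrays and 9.41 to 9.59 on the 6 dental arrays. No explanation was tested.

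The 6 arrays of each comparison were also split into 3 and 3 in every other way, which makes 10 splits with the real one. In each comparison 1 split, the real one, gave as many calls, with 2366 clusters for embryo against adult, 4068 for embryo against mESC and 6335 for adult against mESC. The highest of the other splits gave 0 in limma. Each other split mixes the groups, whose difference then enters the spread, so low counts were built in. At an unadjusted p under 0.05 the real splits gave 9752, 14318 and 16316 clusters and the highest others 2283, 1857 and 1008. With 10 splits no share under 0.05 can be had. The split of the 6 dental arrays by processing day called 0 clusters in limma, with 804 at an unadjusted p under 0.05. Both days held embryo and adult arrays, so the difference of stage entered the spread here too. The 0 therefore does not exclude an effect of the day.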

How the results depend on the processing

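The fits with the processing day, those with the embryo columns of 1 name averaged and the naming of clusters with several symbols were chosen only after the data were seen. Apart from the thresholds and the fits within a single day, no alternative run moved any of 5 counts of calls by over 1.5 times. Outside the arrays left out, counts within that margin ran from 1965 to 2850 for embryo against adult, 3859 to 5795 for embryo against mESC, 5596 to 8469 for adult against mESC, 2844 to 4361 for both dental groups against mESC and 1431 to 2006 for embryo and mESC against adult. Leaving out each array in turn gave 1944 to 2493, 3664 to 4145, 6107 to 6431, 2867 to 3167 and 1398 to 1812. Without a minimum fold the 5 counts were 5805, 10116, 13354, 8105 and 4252, and at the stricter threshold 559, 1230, 2102, 915 and 388, as the thresholds themselves imply. With the arrays of the second day alone embryo against adult gave 1406 and embryo and mESC against adult 1075, with 1 adult array left whose spread is assumed to be that of the other groups; with the first day alone limma gave 0, on 3 arrays and 1 residual degree of freedom, with 5603 at an unadjusted p under 0.05.

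With a replicate block the 5 counts were 2321, 3986, 6298, 3097 and 1655. Deviations of same-numbered arrays correlated at -0.14 to 0.16. Differently numbered arrays were not set beside them, so these values do not decide whether the numbers pair the samples. Among list tests the block lost the CDK inhibitor list for embryo against adult (adjusted p = 0.0522) and gained immediate early genes for embryo against mESC (adjusted p = 0.0437). Over all alternatives, 1975 list tests kept their side of the threshold, 108 lost a call (58 of them with the estimated correlation) and 55 gained 1 (13 of them in fry), and 1 turned direction: endothelium for adult against mESC was up in camera without a call and down in fry (adjusted p = 0.0014). The cause was not tested. List medians whose sign changed with the scaling belonged to lists that were not called.

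Of the genes the naming rule admits, Barx2, Cdkn1a, Eng, Fgfr3, Igfbp5, Klf2, Krt15, Krt18, Nfkbiz, Notch2, Postn, Sfrp2 and Sox2 lost their call for embryo against adult without some 1 array, Btg1 and Tyrobp for embryo against mESC, and Cdkn1a, Fosb and Wfdc2, among others, for adult against mESC. Within the second day alone 26, 3 and 7 of the admitted genes lost it. Of the clusters 3.22% in mESC, 4.57% in adult and 4.17% in embryo had no spread at all over 3 arrays, also well above background (Wif1 at 11.09 on each embryo array). Quantile normalisation and median centring moved the median of all clusters to no more than 0.07.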

Other observations

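Chosen only after the result was seen were the gene families, the patterns across groups, and the tests of an epithelial share, of dilution and of scaling, and the counts by array of the second marker lists. With 1 cluster kept per gene, embryonic dental cells stood above both other groups at 292 genes and below both at 142. Among the former were Capn6 (12.63 ± 0.06 in embryo, 7.33 ± 0.29 in adult and 5.37 ± 0.32 in mESC, mean ± SD, n = 3), the retinoic acid-degrading Cyp26c1 (15.49 ± 0.55, 11.93 ± 0.78 and 4.32 ± 0.1), the chemokine receptor gene Cxcr4 (12.71 ± 0.77, 9.8 ± 0.43 and 4.56 ± 0.38) and the nuclear receptor gene Nr2f2 (8.99 ± 0.63, 6.08 ± 0.07 and 4.84 ± 0.12). Among the latter were Acta2, which encodes a smooth muscle actin (6.85 ± 0.44 in embryo, 11.96 ± 0.71 in adult and 11.32 ± 0.57 in mESC), the fatty acid oxidation gene Cpt1a (6.58 ± 0.47, 10.94 ± 0.2 and 11.62 ± 0.3) and the matrix gene Tnc (6.67 ± 0.89, 13.03 ± 0.73 and 10.98 ± 0.74). Adult cells stood above both at 817 genes and below both at 870, and mESC above both at 1899 and below both at 1233.

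Of 14 gene families tested with camera (42 tests, adjusted together), the aminoacyl-tRNA synthetases were 14 lower of 16 in adult against mESC (median -2.11, adjusted p = 9.35e-11), 8 lower in embryo against mESC (median -1.1, adjusted p = 5.05e-09) and 4 higher in embryo against adult (median 0.84, adjusted p = 9.35e-11), with adjusted p = 0.0763, adjusted p = 0.0871 and adjusted p = 0.0763 with an estimated correlation. Protocadherins were 14 higher of 20 in adult against mESC (median 1.25, adjusted p = 5.83e-10, and adjusted p = 0.0442 with an estimated correlation). They were 3 higher in embryo against mESC (median 0.59, adjusted p = 6.47e-06) and 3 lower in embryo against adult (median -0.6, adjusted p = 1.74e-06). With an estimated correlation these 2 were not called (adjusted p = 0.0635 and adjusted p = 0.0614). Protocadherin genes have similar sequences, and signal shared between their probe sets was not tested. Semaphorins were 9 higher of 19 against mESC in embryo (median 0.67, adjusted p = 6.15e-08, and adjusted p = 0.0442 with an estimated correlation) and 9 higher in adult (median 0.76, adjusted p = 8.19e-06, and adjusted p = 0.0614 with an estimated correlation). None of the family medians given here changed sign under quantile normalisation or median centring. Other families called in camera, such as collagens, are not described.

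Most markers of macrophages (11 of 15) and some of mesenchyme (5 of 18) were higher in adult than in embryonic cells. Of a second list of macrophage genes, written before their values were looked at, 18 of 23 measured were called higher in adult (78.3%, against 2.87% of all genes), with Mrc1 at 12.77 in adult and 4.64 in embryo, and of a second mesenchyme list 12 of 22 (54.5%), with Ogn at 14.27 and 5.55. A lower share of epithelial cells that raises every other cell type alike would give like medians. The medians (embryo minus adult) ranged over 2.85 log2 units, with an SD over members of at most 2.47. They ran from -2.79 for macrophages and -1.2 for mesenchyme to -0.28 for endothelium, -0.21 for Schwann cells and 0.06 for neurons. The range goes against an equal rise only, and it includes the lists that raised the question. Genes near the background would read near 0 whatever the share, and a rise that differs by cell type was not tested. A lower epithelial share thus stays open. RNA of macrophages and of mesenchyme in the adult samples remains a candidate source, and how far the sort for living GFP+ cells removed such cells was not measured here. For mesenchyme the bound, a majority of the second list, was missed without adult replicate 2, embryo replicate 2 or embryo replicate 3 (10 of 22 each). It was also missed without any 1 mESC replicate (11 of 22). Adult replicate 1, the array farthest from its group, held the highest adult value for 20 of the 22 genes. Expression of these genes by the sorted cells themselves, at another age and site, stays open and was not tested.

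Cell cycle genes were higher in embryonic than in adult cells (median 1.74). Dilution of the adult signal by RNA of other cells, as the whole cause, is argued against by the epithelial keratins and junctions, whose median was -0.01 (0.05 with median centring), so that the lists lay 1.75 log2 units apart. This is little more than the spread of the epithelial genes, which went both ways (SD 1.69 over members). Under quantile normalisation or median centring the lowest median of the cell cycle list was 1.59. The median difference of all clusters was 0.01 as deposited and 0.02 and 0.07 under these scalings. They thus had little shift to remove and could move the list little, so they do not decide whether scaling of the arrays plays a part. A lower share of dividing cells in the adult labial cervical loop is a hypothesis that these arrays do not test, and age and tissue differ together.

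Enamel transcripts were raised on mESC replicate 2 over the other mESC arrays, by 2.26 log2 units for Amelx, 2.48 for Ambn and 1.48 for Enam, and these genes were also highest on 1 of the embryo arrays, replicate 2 (Amelx 7.23 against 5.79 and 4.92, Ambn 7.67 against 6.72 and 5.74, Enam 8.82 against 6.94 and 8.07). If adult RNA or target was carried over to that array, other genes bright in adult and dim in mESC should be raised too, by a median of 0.47 at the share of 0.0238% that Amelx gives. The median excess of the 3 such genes was 0.22, against -0.3 (3 genes) on mESC replicate 1 and 0.23 (4 genes, chosen anew for each array) on mESC replicate 3. The bound written beforehand against carry-over, no higher than on the other mESC arrays, was thus met against mESC replicate 3 and not against mESC replicate 1, and the rule that fewer than 10 genes decide nothing was added after the result was seen. The bound for carry-over, also written beforehand, was an excess of at least 1/2 of the 0.47, which the 0.22 missed narrowly and on 3 genes. By its control values embryo replicate 2 was the embryo array of the first day, which also held 2 adult arrays, whereas all mESC arrays were of the second. Carry-over stays open, and no biological explanation was tested.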
